A study of Drosophila melanogaster with 9 samples.

How the data were processed

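RNA of stage 11 Drosophila melanogaster embryos was measured on 9 custom Agilent expression arrays in 1 colour (Cy3). Per the labels, 3 arrays held wild type (w1118) RNA, 3 held RNA of embryos null for yan, the gene now called aop (anterior open), and 3 held RNA of embryos null for pointed (pnt). The array carried 8959 probes under 1018 gene identifiers, which per the labels stand for putative targets of the Yan repressor, so all counts refer to that choice of genes and not to the whole genome.

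Per the file headers, the deposited spot intensities came from Agilent Feature Extraction 9.5.1.1, which subtracted a local background and removed spatial and multiplicative trends within each array. No scaling between arrays is recorded there. The deposited files also hold other columns with a flag per spot, per the file headers, for spots well above background, saturated spots and outliers. The series matrix held the same processed intensity rounded to 3 digits, with a difference from the scanner values of at most 0.497%, so its scale, centring and direction were known. Its column medians were 28.2, 24.5 and 21.3 in wild type replicates 1, 2 and 3, 22.2, 27.7 and 28.1 in the yan null replicates, and 22.9, 25.45 and 20.95 in the pnt null replicates.

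Each array was scaled in R 4.3.3 by taking log2 of the processed signal and subtracting the array's 75th percentile over its 15208 non-control spots. Outlier spots were left out, spots of a probe were averaged, and a probe was kept if it was well above background on all arrays of at least 1 group and had a value on every array. This left 6673 probes, whose mean within a gene gave 920 tested genes with a median of 4 probes each; 146 genes had 1 probe. The gene was taken as the identifier in the first part of each probe name. Symbols came from a RefSeq gene table (assembly Release 6 plus ISO1 MT), while the array design is on dm3 per the file headers, so no coordinates are printed. That table held a match for 632 of the CG and CR identifiers (625 and 29), and for 5 of 303 FBgn identifiers, and 61 identifiers were of other Drosophila species; 581 tested genes thus had a symbol, and 420 had a name other than an annotation number.

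The arrays' 75th percentile signals ran from 124 to 167 and 76.4 to 80.6% of spots were well above background, with 0 saturated spots. The number of arrays limits the precision: the median standard error of a log2 difference was 0.09. A group whose arrays all lay below background has only a bound on its fold change, against the lowest signal well above background; a gene counts as such only if all its probes do, and no named gene was of that kind.

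All 9 arrays entered 1 linear model with a mean per genotype in limma 3.58.1 (lmFit and eBayes, two-sided moderated test). Adjusted p-values are Benjamini-Hochberg values over the 920 genes, with a call at 0.05. The comparison of the mutants with each other is also the test of whether their effects against wild type differ. The 27 gene lists were written before the data were examined. Their members were matched to tested genes by symbol, so 272 tested genes known by FBgn identifier only could not be counted on any list. List counts below therefore cover only members matched by symbol, and other members may have been measured. Of the lists, 11 had at least 5 matched genes and were tested with camera at a preset correlation of 0.01. These p-values were adjusted over the 11 lists, and camera was run again with an estimated correlation. Because both mutants were compared with the same 3 wild type arrays, 100 simulated data sets of unchanged groups gave the overlap and correlation that shared controls alone produce.

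Genes named in the text followed a rule: aop and pnt; the 12 largest rises and falls per mutant among called genes whose groups did not overlap, with 8 each between the mutants; the 10 largest changes shared by the mutants in the same direction and in opposite directions; and up to 4 called genes per list, or every called gene for the EGFR lists. Exceptions are stated where they occur. The labels do not say whether replicates came from separate collections of embryos, so p-values measure the spread between these samples, which may be technical.

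The arrays fell into 2 sets scanned together, taken here as slides 1 and 2. Slide 1 held the 3 wild type arrays and yan null replicates 1 and 2; slide 2 held yan null replicate 3 and the 3 pnt null arrays. Fits with slide as a fixed block, as a random block and within each slide were run, the last for yan null against wild type on slide 1 and pnt null against yan null on slide 2. The other alternatives were other backgrounds, scalings and filters, other fits and thresholds, probes in place of genes, the replicate number as a block and each array left out in turn.

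On simulated data for the 920 genes with 200 changed, the fit recovered 90% of 1.5-fold and 96% of 2-fold changes for yan null against wild type, 88 and 92% for pnt null against wild type, and 82 and 96% for pnt null against yan null. It also called 12, 8 and 7 unchanged genes in those comparisons.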

Results

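Expression of 920 genes, chosen on the array as putative targets of the ETS repressor Yan, was measured in stage 11 embryos of 3 genotypes with 3 arrays each. Of these, 52 stand under identifiers of other Drosophila species and stay in all counts. Among those 52, 21 were called for yan null against wild type, 26 for pnt null against wild type and 11 between the mutants. Yan and Pointed are antagonistic ETS transcription factors downstream of receptor tyrosine kinases (RTKs) such as the EGF receptor, Yan a repressor and Pointed an activator. The design asks which of these genes change when either factor is lost, and whether they change in opposite directions or together. Arrays of 1 genotype correlated across genes at r between 0.980 and 0.994.

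The mutated genes themselves were not lower. The aop transcript stood at a log2 difference of 0.07 in yan null embryos (SE 0.06, n = 3 per group, limma adjusted p = 0.435), and its 8 probes ranged from -0.31 to 0.57. The pnt transcript stood at 0.13 in pnt null embryos (SE 0.09, limma adjusted p = 0.274), and its 18 probes ranged from -0.65 to 0.42. In yan null embryos pnt was called higher by 0.26 (limma adjusted p = 0.0477), a call that ended without wild type replicate 2 or 3, yan null replicate 1 or 2, or any single pnt null array (adjusted p 0.0632 to 0.127). For aop in pnt null embryos the difference was 0.12 (limma adjusted p = 0.169). With the median of a gene's probes in place of the mean, aop stood at -0.29 in yan null (adjusted p = 0.0510) and pnt at 0.38 in pnt null embryos (adjusted p = 0.0314). Null alleles can leave a transcript in place, so these probes check nothing about the genotype labels.

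In yan null embryos the steepest rise among named genes with several agreeing probes was that of argos (aos), the secreted inhibitor of the EGF receptor. It rose 4.56-fold over wild type (log2 fold change 2.19, SE 0.07, n = 3 per group, limma adjusted p = 3.9e-07), and its 8 probes ranged from 2.08 to 2.36. The muscle regulator nautilus (nau) rose by 1.39 on the log2 scale (SE 0.12), the mesodermal FGF receptor gene heartless (htl) by 0.89 (SE 0.08), arginase (arg) by 1.35, dao by 1.22 and king tubby (ktub) by 0.92. The Toll family gene Toll-9 rose by 1.77 in the mean of 3 probes, 2 of them not well above background in wild type and higher by at least 2.07-fold and 1.37-fold. The falls were led, among named genes with several probes, by rigor mortis (rig, -2.53, SE 0.14), the poly(A) polymerase gene wispy (wisp, -2.47, SE 0.27), the innexin gene zpg (-1.63) and the RNA-binding protein gene orb (-1.47). The cell death activator reaper (rpr) fell by 1.19, the methuselah receptor gene (mth) fell by 1.27, PHDP fell by 1.42 and Cad96Ca fell by 1.33. The size of the PHDP fall is uncertain. Its yan null levels (-4.68 to -4.98) lay near the lowest signal well above background on those arrays (-4.69 to -5.14). Cad96Ca stood at -4.29, -3.30 and -4.28 in yan null replicates 1, 2 and 3. Trf4-2 (-5.0) and GstD4 (-1.93) each rest on 1 probe, well above background on 2 of the 3 yan null arrays.

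Outputs and feedback genes of RTK signalling rose together in yan null embryos: 8 of the 10 genes matched by symbol on that list rose and 0 fell, and 8 were called adjusted over the list alone. Besides aos these included edl (0.67), which encodes an antagonist of Yan, the feedback inhibitor sprouty (sty, 0.59), the ligand-processing protease rhomboid (rho, 0.51), sv (0.48) and phyl (0.40). The others were pnt and ttk, whose calls ended in 7 and 4 fits that left out an array. The ttk call also ended with slide as a fixed block (0.30, limma adjusted p = 0.0664). With the median of a gene's probes ttk stood at -0.13. The list's camera adjusted p was 0.00120, and adjusted p = 0.0980 with an estimated correlation. Among 7 measured EGFR, Ras and MAPK components, rho and Star (S, 0.36) rose and the rhomboid-family gene ru fell (-0.67); camera adjusted p was 0.913, and 3 were called adjusted over the list alone. The ru call ended with slide as a block, which here equals leaving out yan null replicate 3 (-0.60, adjusted p = 0.0916). It also ended without wild type replicate 2 or 3 or yan null replicate 1 (adjusted p 0.0722 to 0.0960), and its 5 probes ran from -1.99 to 0.03.

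Notch pathway and Enhancer of split genes rose as a group in yan null embryos, with 13 of 16 called higher, 0 lower, and 13 called adjusted over the list alone. E(spl)mgamma-HLH rose by 0.71, E(spl)m5-HLH by 0.64, E(spl)m7-HLH by 0.61 and the Notch inhibitor gene numb by 0.57; camera adjusted p was 6.8e-05, and adjusted p = 0.224 with an estimated correlation. Mesoderm and muscle progenitor genes had 9 of 14 higher and 2 lower (12 called adjusted over the list alone), among them nau, htl and eve (0.83); camera adjusted p was 0.00665, and adjusted p = 0.264 with an estimated correlation. CNS midline genes had 8 of 11 higher and 0 lower (8 over the list alone), with sim at 0.27; camera adjusted p was 0.0137, and adjusted p = 0.348 with an estimated correlation. Segmentation and Hox genes had 7 of 10 higher and 0 lower (7 over the list alone), with lab at 0.47; camera adjusted p was 0.00529, and adjusted p = 0.224 with an estimated correlation. Several genes stand on more than 1 list, such as aos, rho and pnt on the RTK and midline lists. Kr counts among the higher mesoderm and segmentation genes. With only probes well above background on all 9 arrays it stood at -0.0024 (limma adjusted p = 0.992). Of the other higher segmentation genes, Antp stood at -0.11 with the median of a gene's probes. The calls of en and wg ended in 5 and 3 fits that left out an array.

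For yan null against wild type, 376 genes were called, 198 higher and 178 lower, of which 60 changed at least 2-fold (19 higher, 41 lower). The 3 yan null arrays lay wholly outside the wild type range for 499 genes (54.2%, where chance gives 10%). With slide as a fixed block 323 genes were called, 306 of them the same genes in the same direction, and on slide 1 alone 268 were. The 5 lists kept adjusted p-values of at most 0.00801 with the block and at most 0.0101 on slide 1. With the median of a gene's probes the mesoderm and segmentation lists had adjusted p of 0.0610 and 0.0892, and eve was not called (log2 difference 0.46, adjusted p = 0.0624). Centring on spike-in controls moved the median of all 920 genes from 0.02 to 0.40 and the share of higher calls from 52.7 to 90.4%, so all directions are relative to the bulk of the array's genes.

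In pnt null embryos pxb rose by 1.12 on the log2 scale (SE 0.05, n = 3 per group, limma adjusted p = 3.5e-06), tinc by 1.08 (SE 0.11), raskol, a Ras GTPase-activating protein gene, by 0.93, and the insulin-binding protein gene ImpL2 by 0.89. The transcription factor gene bab2 rose by 0.80, stx by 0.78 and the matrix metalloproteinase gene Mmp2 by 0.78, although 2 Mmp2 probes carried most of its mean, 1 at 3.0 and 1 not well above background in wild type and higher by at least 8.10-fold. The falls included Nepl12 (-2.73, 1 probe), rig (-2.16), wisp (-2.12), mth (-1.86), qkr54B (-1.62), zpg (-1.60), orb (-1.43) and the integrin subunit gene scab (scb, -1.50, SE 0.09). aos fell by 0.51 (limma adjusted p = 8.1e-04), the EGF receptor ligand gene spitz (spi) fell by 0.48 and Ras85D fell by 0.59. Those 3 falls had adjusted p = 0.0880, 0.122 and 0.246 with slide as a fixed block, where aos stood at -0.44, spi at -0.37 and Ras85D at -0.37, and none of them was called with spike-in centring. Probes of pxb, bab2, scb, orb and qkr54B lay over 4-fold apart within the gene, and pxb probes ran from -0.54 to 3.19.

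The RTK output list did not shift in pnt null embryos: aos and ed fell, 8 of 10 genes were not called, and edl stood at -0.23, phyl at -0.13, sty at 0.18 and rho at 0.09 (camera adjusted p = 0.974; 2 called adjusted over the list alone). The fall of ed (-0.29) rested on the mean of its 18 probes, whose median stood at 0.16. Its call also ended with slide as a fixed block (-0.20, limma adjusted p = 0.272). Of the 7 EGFR, Ras and MAPK components, spi and Ras85D were the 2 that fell (camera adjusted p = 0.787; 2 over the list alone).

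Notch pathway and Enhancer of split genes were higher in pnt null embryos too, with 10 of 16 rising and 1 falling, and 13 called adjusted over the list alone. E(spl)mbeta-HLH rose by 0.71, E(spl)m7-HLH by 0.61, E(spl)m5-HLH by 0.58 and E(spl)mgamma-HLH by 0.47; camera adjusted p was 0.00643, and adjusted p = 0.554 with an estimated correlation. With slide as a fixed block the list had adjusted p = 0.00323, but that fit contains the yan null difference and is no separate support. In it the calls of E(spl)mbeta-HLH (0.88, adjusted p = 0.0571) and E(spl)mgamma-HLH (0.45, adjusted p = 0.0714) ended. Mesoderm genes matched by symbol had 7 of 14 higher and 0 lower (7 over the list alone), with midline (mid) at 0.55 and slouch (slou) at 0.54. Segmentation genes matched by symbol had 6 of 10 higher and 0 lower (6 over the list alone), with lab at 0.45 (0.40, limma adjusted p = 0.184, with slide as a block). The camera adjusted p of these 2 lists was 0.0384 each, and adjusted p = 0.554 each with an estimated correlation. With the slide block these were 0.0470 and 0.131, and both calls ended when the gene Kr was left out (adjusted p = 0.144 each). Without wild type replicate 2, pnt null replicate 1 or pnt null replicate 3, 1 list in place of 3 was called. With the median of a gene's probes in place of the mean, adjusted p was 0.0902 for mesoderm and 0.380 for segmentation genes.

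For pnt null against wild type, 393 genes were called, 192 higher and 201 lower, of which 54 changed at least 2-fold (14 higher, 40 lower). The groups did not overlap for 480 genes (52.2%, where chance gives 10%). Wild type and pnt null arrays lay on different slides, which only yan null arrays link. With slide as a fixed block 116 genes were called, all 116 among the same genes in the same direction. With slide as a random block 441 were, but the correlation within slide was estimated at -0.059. Since these 2 genotypes share no slide, the random block does not correct this comparison for slide. The share of higher calls was 48.9%, against 81.8% with spike-in centring, which moved the median of all genes to 0.26, and 21.6% with no scaling.

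Set directly against each other, pnt null embryos had less aos than yan null embryos by a log2 difference of -2.70 (SE 0.07, n = 3 per group, limma adjusted p = 2.2e-07). Nepl12 was lower by -2.72, qkr54B by -1.59 (-0.70 with only probes well above background on all 9 arrays), nau by -1.56 (SE 0.12), dao by -1.45, wit by -1.39 and htl by -0.99 (SE 0.08). Higher in pnt null than in yan null embryos were Acat1 (1.37), veil (1.0), PHDP (0.89), pxb (0.88), rdhB (0.84) and tinc (0.72). The size for PHDP is uncertain, since its yan null levels lay near the lowest signal well above background. Toll-9 was lower by -1.36, a call that ended with the slide block at an unchanged -1.36 (adjusted p = 0.145) and without yan null replicate 1 (adjusted p = 0.0573). Its probes were well above background on at most 2 of the 3 pnt null arrays, so that size is uncertain.

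The RTK output list differed between the mutants, with 6 of 10 genes lower in pnt null embryos and 0 higher (7 called adjusted over the list alone): aos, edl (-0.89), phyl (-0.54), rho (-0.42), sty (-0.41) and ed (-0.33). Its camera adjusted p was 9.3e-04, and adjusted p = 0.0739 with an estimated correlation. The call for ed rested on the mean of its probes, whose median stood at 0.01. CNS midline genes had 6 of 11 lower and 0 higher (6 over the list alone), among them comm2 (-0.70); camera adjusted p was 0.00861, and adjusted p = 0.611 with an estimated correlation. Neuroblast and proneural genes had 6 of 9 lower and 1 higher (7 over the list alone), the last being Dr (0.62), and camera adjusted p was 0.0366, and adjusted p = 0.611 with an estimated correlation. That call also ended without Kr (adjusted p = 0.0825) and with the median of a gene's probes (adjusted p = 0.0736). The 3 lists had adjusted p of 3.5e-04, 0.0207 and 0.0207 with slide as a fixed block, and on slide 2 alone 0.00106, 0.0370 and 0.0370. Both fits rest on the 1 yan null array of slide 2 and are no separate support. Among EGFR, Ras and MAPK components 5 of 7 were lower (6 called over the list alone), and camera adjusted p was 0.193. All 5 calls ended with slide as a fixed block: rho (-0.32, adjusted p = 0.114), spi (-0.25, 0.196), S (-0.16, 0.354), Ras85D (-0.24, 0.365) and Egfr (-0.13, 0.420).

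Between the mutants, 247 genes were called, 99 higher and 148 lower in pnt null embryos, of which 37 differed at least 2-fold. The groups did not overlap for 430 genes (46.7%, where chance gives 10%). With slide as a fixed block 108 genes were called, 105 of them the same genes in the same direction, and on slide 2, which holds 1 yan null array, 40 were. The call for sty ended with that block at a similar difference (-0.42, adjusted p = 0.0530). That fit rests on 1 yan null array. On slide 2 alone aos, nau and htl were called, and edl (-0.83, adjusted p = 0.0850) and phyl (-0.61, adjusted p = 0.0621) were not. The share of higher calls was 40.1%, against 20.4% with spike-in centring, 18.6% with no scaling and 51.5% with normexp background correction and quantile normalization together (47.4% with quantile normalization alone).

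Many genes were called in both mutants against the same wild type arrays. Genes called in both mutants in the same direction numbered 226 (112 higher, 114 lower), against 80.2 for independent lists and 0 in simulated unchanged groups that shared the wild type arrays. Genes called in opposite directions numbered 19, against 80.4 for independent lists. Independent lists leave out the shared controls and the simulation leaves out real effects, so neither measures a shared effect. The shared rises included E(spl)m7-HLH (0.61 in both) and dpp (0.53 in yan null, 0.48 in pnt null, with the yan null call resting on the mean of its probes, whose median stood at 0.17), and the shared falls rig, wisp, zpg, orb, rpr (-1.19 and -0.75) and the cyclin gene CycB (-0.49 and -0.64). The opposite changes were led by aos and by wit (0.84 in yan null, -0.55 in pnt null), whose pnt null call ended without wild type replicate 2 (adjusted p = 0.0583), wild type replicate 3 (adjusted p = 0.0608) or pnt null replicate 3 (adjusted p = 0.0503). The slide block left 91 genes called in both in the same direction and 2 in opposite directions, in a fit where the pnt null difference contains the yan null one and agreement is partly built in. The count of 19 was 9 without wild type replicate 3, 11 without yan null replicate 1 and 11 without pnt null replicate 3.

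**Figure D1:**
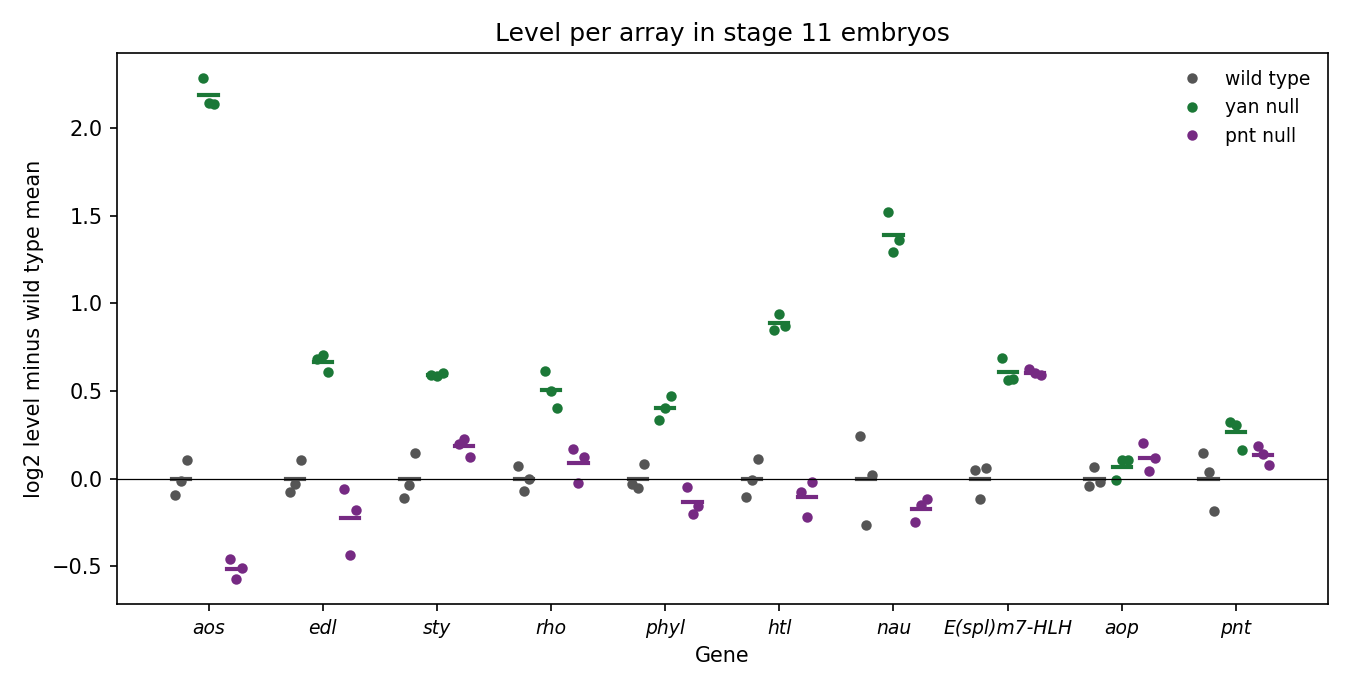
Level of 10 genes on each array as log2 level minus the wild type mean (vertical axis), with a point per array, a bar at the mean of 3 arrays and a colour per genotype. aos, edl, sty, rho, phyl, htl and nau were higher in yan null embryos, aos fell by 0.51 in pnt null embryos, and E(spl)m7-HLH stood at 0.61 in both mutants.

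**Figure D2:**
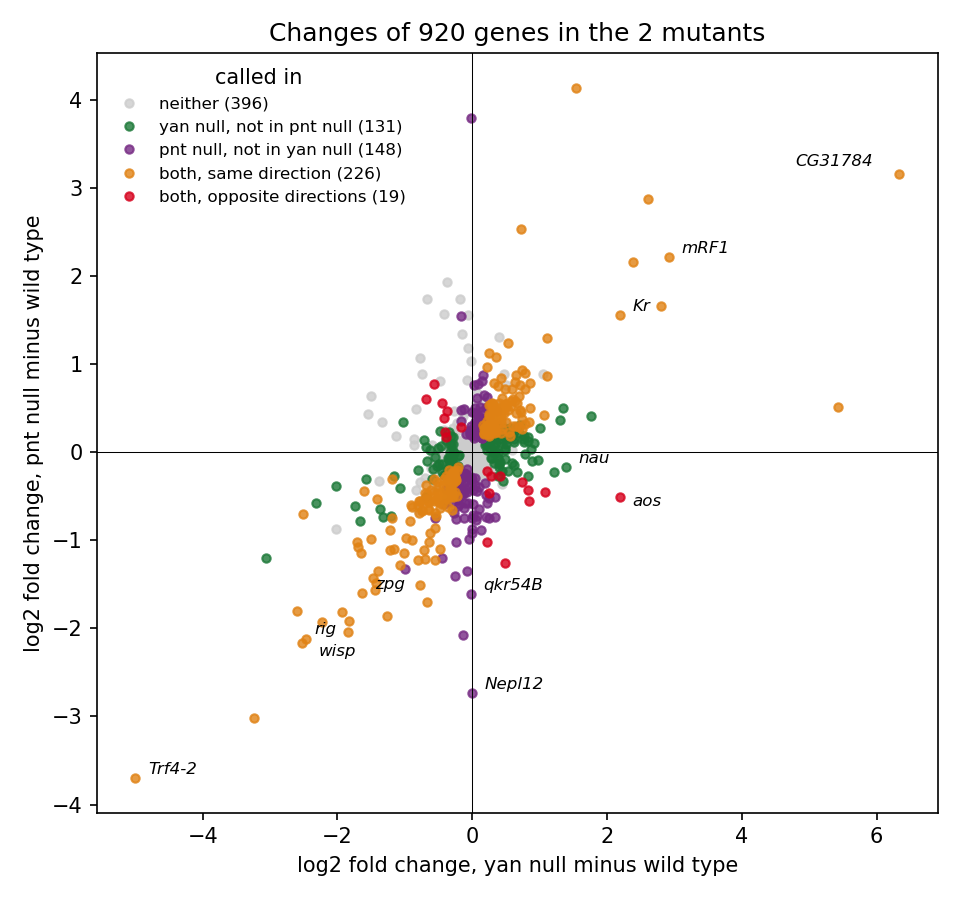
Log2 fold change of 920 genes in yan null (horizontal axis) and pnt null embryos (vertical axis) against the same wild type arrays, with a point per gene coloured by the comparisons in which it was called. Most genes called in both lie on the rising diagonal (226), and 19 lie in the opposite quadrants, among them aos.

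Across genes the fold changes in the 2 mutants correlated at Pearson r 0.614 and Spearman rho 0.571, where unchanged groups sharing the controls gave 0.484 and 0.462. Sharing controls gives such an r when nothing changes, so 0.484 is not the part of 0.614 owed to the controls. Genes are not independent replicates. The covariance was 0.237 against 0.0173 in the simulation, a difference of 0.220, and 73.4% of genes had the same sign in both against 66.9%. The 3 wild type arrays cannot be split so that each side keeps at least 2, so part of the excess in shared calls may come from the shared controls. Of 131 genes called in yan null embryos and not in pnt null embryos, 75 differed between the mutants by the direct test, nau and htl among them, and so did 73 of the 148 called the other way round, Nepl12 among them.

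Among named genes, the largest rises common to both mutants rest on few probes. Kr, a gap gene later active in muscle and the nervous system, had a gene mean of 2.20 in yan null and 1.55 in pnt null embryos, but 2 of its 6 probes, dim in wild type with a spot well above background on 2 and 3 of the 3 arrays, rose by 6.56 to 6.62 and by 5.77 to 5.79, and the others ranged from -0.31 to 0.34 and from -0.79 to -0.17. With only probes well above background on all 9 arrays, Kr stood at -0.0024 in yan null embryos (adjusted p = 0.992) and at -0.56 in pnt null embryos (adjusted p = 0.00434). mRF1, a mitochondrial release factor gene, had 1 probe at 5.56 and 4.22 and the other at 0.28 and 0.21. snoRNA:Psi28S-1180 (2.80 and 1.66), tRNA:Asn-GTT-1-4 (-1.44 and -1.57) and tRNA:Leu-CAG-1-5 (-1.39 in yan null) have near-identical copies or short transcripts and are uncertain. Among called genes with several probes, every probe had the same sign in 67.7% for yan null against wild type, 63.0% for pnt null against wild type and 68.2% between the mutants.

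**Figure D3:**
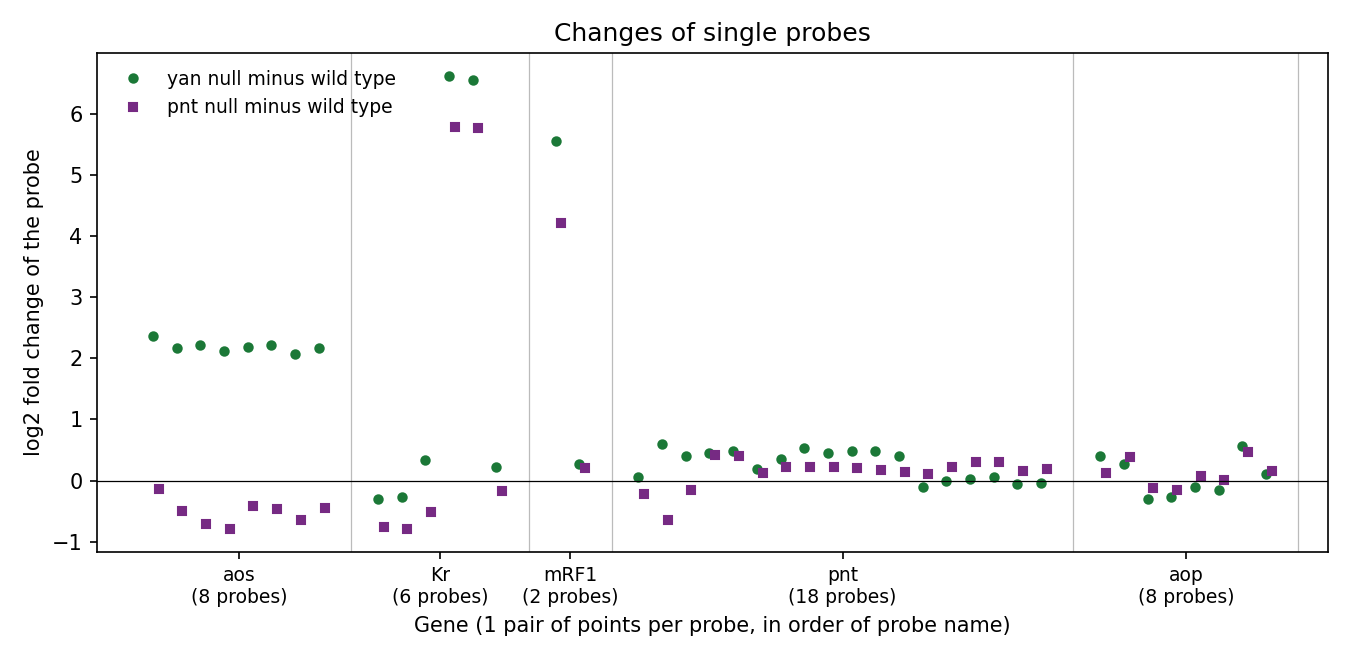
Log2 fold change of single probes (vertical axis) for 5 genes, with a circle for yan null and a square for pnt null against wild type. The 8 aos probes lie together between 2.08 and 2.36 in yan null embryos, whereas the Kr mean of 2.20 comes from 2 of 6 probes and that of mRF1 from 1 of 2.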

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

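The maternal RNA test and the test of single probes of Kr and mRF1 were chosen only after the result was seen; the other tests in this part were set beforehand.

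Named genes called in opposite directions in the 2 mutants against wild type stood out. A difference between the mutants follows from that choice (19 of 19 such genes had one by the direct test), so it adds no evidence. The log2 differences of pnt null minus yan null were -2.70 for aos, -1.39 for wit, a BMP receptor gene measured by 1 probe, -1.26 for wgn, a TNF receptor gene, -1.24 for hng2, -0.70 for comm2, -0.68 for dve and -0.43 for spir. They were 1.0 for veil, 0.62 for Dr and 0.45 for shn. On slide 2 alone, with 1 yan null array, aos was called and wit, veil, comm2, Dr and shn were not (adjusted p between 0.0554 and 0.0997). Calls against wild type also ended: with slide as a fixed block aos, wit, veil, wgn, dve, comm2, Dr, spir and shn were not called in pnt null embryos. The differences there were similar for aos (-0.44), wit (-0.54), veil (0.49), dve (-0.23), comm2 (-0.41), Dr (0.20) and spir (-0.24) and smaller for wgn (-0.29) and shn (0.19). In yan null embryos comm2 (0.26, adjusted p = 0.0580), hng2 (0.22, 0.0700) and spir (0.21, 0.0665) lost their calls with the block. For these genes other than aos and wgn, at least 1 call against wild type also ended when 1 array was left out, which for Dr was pnt null replicate 3 alone. Groups of 3 arrays were too small to look for arrays far from the others.

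The genes orb, wisp and zpg, picked from the largest falls and known from the oocyte and germ line, were lower in both mutants. The germ cell list fixed beforehand had 2 tested genes that could be matched by symbol, zpg and ovo. The gene ovo went the other way (0.14 in yan null, 0.24 in pnt null embryos, limma adjusted p = 0.0138 in the latter). With slide as a fixed block that call ended (0.26, limma adjusted p = 0.227). If wild type embryos held more maternal RNA, other maternal genes should be lower too, yet the median of the 8 others that could be named was 0.028 in yan null and -0.044 in pnt null embryos. The reading was at first that a median above -0.10 argues against maternal RNA; it was changed after the result was seen, because members went both ways, CycB falling (-0.49 and -0.64) and stwl rising (0.57 and 0.53), and several are also transcribed by the zygote. The list could not be matched to 272 tested genes known by FBgn identifier only, some of which fell in both mutants, such as FBgn0000166 (-2.60 and -1.80). Maternal RNA therefore stays open, as does an effect of either genotype, which was not tested apart from it.

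Changes of over 4-fold in the same direction in both mutants were found for 8 genes, 1 of them under an identifier of another Drosophila species and 6 with at least 2 probes. A sequence variant under single probes would leave the other probes of a gene unmoved. In 83.3% of these genes (5 of 6, among them rig and wisp) every probe moved over 2-fold, so single probes do not account for those 5. The exception was mRF1. The genes were picked by the mean over their probes, which leaves out genes where few of many probes moved. The share therefore cannot argue against single-probe variants in other genes. For Kr and mRF1 together, 3 of 8 probes moved over 2-fold in both mutants, so a sequence or transcript difference between stocks at those probes may account for their means, and the arrays cannot separate this from a change of 1 isoform. A difference between stocks that covers a whole gene stays open for the others.

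Genes called in 1 mutant that also differed between the mutants could reflect variation linked to the mutated chromosome, since aop lies on chromosome 2 and pnt on chromosome 3. Of the yan null genes 21 lay on chromosome 2 and 19 on chromosome 3, and of the pnt null genes 20 and 25, among the 47 of 75 and 47 of 73 that had a symbol, an odds ratio of 1.38 (95% interval 0.54 to 3.54, Fisher's exact p = 0.518). The interval is too wide to exclude linked variation, and no biological explanation was tested against it.

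With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real split called 376 genes for yan null, 393 for pnt null and 247 between the mutants, where the highest of the other splits called 0. Only 1 of the 10 splits, the real one, reached each count. Every other split puts both genotypes on each side, so differences between genotypes widen its spread and lower its calls. The 0 is therefore no support for the real split.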

How the results depend on the processing

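The median of a gene's probes, outlier spots kept and lists without Kr were chosen only after the data were seen; the other alternatives were fixed before the data were examined. Of 180 values of named genes 177 were called; 62 of these calls ended with slide as a fixed block (9 for yan null, 32 for pnt null, 21 between the mutants) and 35 in at least 1 fit that left out an array. Over the 27 alternatives that give gene values, 4104 of 4604 values of named genes kept direction and call, 484 lost a call, 1 gained a call and 15 reversed, with aop in yan null and pnt in pnt null left out of that count and given below. That total is no measure of robustness, since nearly all these genes were named because they were called. It also pools alternatives close to the main fit: the series matrix values and slide as a random block each kept 180 of 180 values. Slide as a fixed block kept 118 of 180. With 76.4 to 80.6% of spots well above background, the rest limit what dim probes can show. The cause of each shift below was not tested except where fewer arrays, genes or a stricter threshold give it.

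Spike-in centring called 581 genes for yan null and 340 in both mutants in the same direction; it put aop at 0.45 in yan null and pnt at 0.39 in pnt null embryos, and turned Hs6st (0.081), fz (0.17), trn (0.091) and shn (0.22) in yan null, spir (0.044) in pnt null, and aop between the mutants (-0.077). No scaling called 169, 176 and 129 genes, 81 in the same and 5 in opposite directions, with aop at -0.062 between the mutants. Normexp with quantile normalization gave aop at -0.023 in yan null, pnt at 0.0068 between the mutants and r 0.643. Probes as the unit gave 2384, 2575 and 1647 calls, 1368 in the same and 90 in opposite directions, and r 0.649. An adjusted p of 0.01 left 248, 262 and 139 genes, 142 in the same and 6 in opposite directions; a minimum of 1.5-fold left 143, 124 and 106, with 64 and 1. With slide as a fixed block 116 genes were called for pnt null and 108 between the mutants, 91 in the same and 2 in opposite directions, with r 0.667, in a fit where the pnt null difference contains the yan null one; slide 2 alone gave 40. Array weights gave r 0.653.

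With probes well above background on all 9 arrays Kr stood at -0.0024 in yan null and -0.56 in pnt null embryos, and 1 list was called for pnt null. The median of a gene's probes put aop at -0.29 in yan null and -0.14 in pnt null, pnt at 0.38 in pnt null, ttk at -0.13 and Antp at -0.11 in yan null, and ed at 0.16 in pnt null and 0.0087 between the mutants; 3 lists were called for yan null and 1 for pnt null. For pnt null 1 list was also called with only the arrays of the 2 groups in the fit and with lists without Kr. With an estimated correlation 0, 0 and 0 of the lists were called, against 5, 3 and 3.

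Leaving out 1 array gave 319 to 392 genes for yan null, 326 to 382 for pnt null, 176 to 246 between the mutants, 192 to 223 in the same and 9 to 20 in opposite directions, r of 0.557 to 0.681, 5 to 6, 1 to 3 and 2 to 4 lists, aop at 0.05 to 0.11 and pnt at 0.04 to 0.21. The count in opposite directions was 9 without wild type replicate 3 and 11 without yan null replicate 1 or pnt null replicate 3; 1 list was called for pnt null without wild type replicate 2, pnt null replicate 1 or pnt null replicate 3.

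Deviations of same-numbered arrays correlated at 0.50, 0.63 and -0.07 for yan null and wild type, -0.30, 0.23 and 0.19 for pnt null and wild type, and 0.06, 0.19 and -0.31 for the mutants. Replicates 1 and 2 of yan null and wild type, when crossed, stood at -0.57 and -0.60. Differently numbered arrays reached 0.51 for pnt null and wild type and 0.67 for the mutants. With 3 arrays per group these values do not settle whether the replicate numbers pair the samples. With the replicate number as a block 363, 377 and 230 genes were called, 212 in the same and 14 in opposite directions, and 1 list was called for pnt null.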

Other observations

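Of 8 Wingless pathway genes, 4 rose and 2 fell in yan null embryos (camera adjusted p = 0.851) and 3 rose and 2 fell in pnt null embryos (camera adjusted p = 0.909), with nkd higher in both (0.27 and 0.25) and Apc lower in both (-0.52 and -0.46). The pnt null call of nkd ended with slide as a fixed block (0.28, limma adjusted p = 0.125). Of 8 Dpp and dorsal ectoderm genes, 5 rose and 1 fell in yan null and 4 rose and 2 fell in pnt null embryos, with dpp and C15 (0.41 and 0.40) higher in both (camera adjusted p = 0.126 and 0.561). The heparan sulphate sulphotransferase gene Hs6st, linked to FGF signalling, fell by 0.66 in pnt null and by 0.31 in yan null embryos, and with spike-in centring it stood at 0.081 in yan null embryos. The transcription factor gene salm rose in both mutants (0.40 and 0.56).

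Of 3 cell death genes measured, rpr fell in both mutants, Diap1 rose (0.16 and 0.30) and hid was not called (-0.08 and 0.10). Both Diap1 calls ended with slide as a fixed block (0.14 and 0.25, adjusted p = 0.112 and 0.152). Of 5 cell cycle genes only CycB was called, lower in both mutants (camera adjusted p = 0.851 and 0.909), and of 7 adhesion and axon guidance genes 1 rose and 1 fell in yan null and 2 rose and 2 fell in pnt null embryos (camera adjusted p = 0.851 and 0.974). CG31784, chosen after its values were seen, rose by 6.34 in yan null (SE 0.22) and by 3.15 in pnt null embryos on the log2 scale, with all 5 probes between 5.62 and 7.36 in yan null embryos. FBgn0042110 (2.61 and 2.87) and FBgn0250816 (-3.24 and -3.02), which have no symbol in the table used, likewise changed in both mutants. Few markers of other tissues could be named, and 272 tested genes known by FBgn identifier only were not compared with the lists. Of 3 glial genes pnt and htl rose in yan null embryos and 0 were called in pnt null embryos, and of 2 neuronal genes 0 were called in either.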
